A study of Homo sapiens with 2 samples.

How the data were processed

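RNA was measured in 2 libraries of HEK293 cells, a human embryonic kidney line of epithelial character: 1 untreated control and 1 library from cells given tumour necrosis factor alpha (TNF alpha) at 10 ng/ml for 6 hours. Per the labels' protocols, a directional kit, which keeps the strand of each transcript, was used on total RNA. The submitters' processing notes name FastQC, TopHat2 2.02, Cufflinks 2.1.1, Cuffdiff and the build GRCh37, with no order or role. The annotation release and the settings of these tools are not given in the sources used here.

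The deposited values are the start and end coordinates of exons in a merged transcript catalogue, 1-based, with a locus and a class code for each transcript, a strand for all but 4 assembled ones, and a gene name for those in reference genes. Its identifiers are those of a Cufflinks merge, which joins transcripts assembled from reads with a reference annotation, here of RefSeq accessions. Transcripts with an identifier of the assembler are called assembled, which does not show that reads cover each of their introns. No line holds a count, a coverage or an FPKM value, and no transcript carries the name of a library, so a transcript cannot be assigned to the control or the TNF alpha library. The planned ratio of the 2 libraries per gene was therefore not computed, and the branch of the design fixed for a catalogue without values per library was followed. Reference transcripts stay in such a merge whether or not they were read, so the presence of a gene says nothing about its expression. Read depth is unknown. With 1 library per group and 1 joint catalogue there is no replicate check, and no p-value was computed across genes, which are not replicates.

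The class codes in the catalogue were = (the intron chain of a reference transcript), j (shares at least 1 splice junction with a reference transcript but has another intron chain), o (other overlap), u (intergenic) and x (exonic overlap on the opposite strand). A class j transcript is called a new isoform below, in relation to this reference only. Genes were counted by name, and the background was the 20209 genes with at least 1 class = transcript of 2 or more exons. Each class j transcript was compared with all reference introns and exons of its strand and could hold several of 10 kinds of difference. These were an exon skipped, another pair of known sites, an intron with 1 new donor or acceptor and an intron with both sites new. Others were a retained intron, a new internal, first or last exon, and introns of a second gene beside those of its own. The kind with a second gene needs no splice between the genes. The last kind, called a new combination or recombined, held reference introns only and none of the other differences. It also takes in transcripts that follow part of 1 reference chain with a changed end.

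Before the data were examined, 26 gene lists were fixed, 11 of them of RNA-binding protein (RBP) genes, with the union of those 11, the union of the TNF receptor signalling and NF-kB target lists, and marker lists for HEK293 and 5 other cell types. For each list, the share of members with a new isoform was set beside 10000 random lists of the same size, drawn from genes of the same class of reference transcript number and largest exon number. A list is called above when its percentile was over 97.5 and below when it was under 2.5. This describes the catalogue and is not a test across replicates. As a check, 200 lists of 60 genes each were drawn at random from the 20209 genes of this catalogue, with fewer random lists beside each. Called above were 1.5% of unchanged lists and 66.5% of lists drawn with odds of 2 for genes with a new isoform. Genes were drawn independently, so the check does not cover lists of related genes. The naming of differences was checked on toy transcripts. Shares of transcripts, introns or exons carry 95% Wilson intervals, which cover counting error only.

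The genes named by rule were TNF, TNFRSF1A and TNFRSF1B, the up to 3 members of each list with the most class j transcripts (ties in alphabetical order), the 10 genes with the most in the catalogue, and the 3 class u loci with the most exons in 1 transcript. Some genes that this rule names are not reported here. Other genes were named after their values were seen. Alternatives fixed beforehand were a requirement for a new intron, for at least 3 exons, loci in place of names, classes j, o and x together, other matching of the random lists, a smaller RBP union, and class u transcripts of 2 or more exons or of at least 200 bases. Splice site sequences of new introns were not analysed here, since no genome sequence of GRCh37 was used here. GENCODE release 29 is on another build, so its transcripts were compared by the lengths of introns and exons within genes of the same name, and no coordinates were mixed. Of the 6793 genes with a new isoform, 6308 had a GENCODE gene of that name. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Coordinates are on GRCh37.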

Results

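The study asked how TNF alpha, an inflammatory cytokine, regulates genes of RNA-binding proteins in relation to metabolic syndrome. It held 1 control and 1 TNF alpha library of HEK293 cells, and the measurement used here was the joint catalogue of transcripts assembled from them. The catalogue held 64874 transcripts of 23560 gene names in 29866 loci. Of these, 43476 were reference transcripts and 21398 (33.0%) carried an identifier of the assembler and are called assembled. No value belongs to a single library, so no gene is described as higher or lower after TNF alpha, and read depth is unknown. Among the assembled transcripts, 13285 were class j, 5580 class u, 1780 class =, 565 class x and 188 class o.

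New isoforms of reference genes. New isoforms were assembled for 6793 of 20209 reference genes (33.6%), with 1 isoform for 3503 genes and 5 or more for 406. ATXN3, which encodes a deubiquitinase, had the most, 25 new isoforms on chromosome 14 (92524896 to 92572965, minus strand). All 25 held reference introns only, in a gene of 31 reference transcripts. PDE4DIP and PPFIA2 had 13 each, CDKN2B-AS1 and PLEKHG5 12 each, and ALG13, POLL, SCMH1, SETD5 and SYBU 10 each. All 13 isoforms of PPFIA2 and all 12 of CDKN2B-AS1, a long noncoding RNA, held known introns only, without another difference. SETD5 (chromosome 3, 9439403 to 9519838, plus strand), a gene of the SET domain family, had 1 reference transcript, and its 10 isoforms all used new splice sites, with a new internal exon in 7 and a new first exon in 4. All 12 isoforms of PLEKHG5 (chromosome 1, 6526152 to 6580121, minus strand) retained an intron and ran into exons of TNFRSF25. All 10 isoforms of SYBU skipped exons, among them one of 204 bases (chromosome 8, 110592028 to 110592231).

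A new donor or acceptor was the most frequent difference, in 5748 transcripts of 3545 genes. Isoforms with reference introns only and no other difference, the new combinations, made up 3193 transcripts of 2210 genes. Of these genes, 584 had 1 reference transcript, so no second one to combine. Skipped exons were found in 2499 transcripts of 1658 genes, new first exons in 2693 of 1784 and introns with both sites new in 2058 of 1265. Retained introns were found in 1487 transcripts of 954 genes, new internal exons in 1268 of 765, new last exons in 1026 of 730 and introns of a second gene in 479 of 234. The catalogue held 9862 introns found in no reference transcript, of which 5708 (57.9%) had 1 new site, 2191 (22.2%) joined known sites and 1963 (19.9%) had both sites new. With at least 1 such intron required, 5059 genes (25%) had a new isoform. With the intron chain of a GENCODE 29 transcript required, a setting chosen after seeing the data, 1412 genes (6.99%) did.

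**Figure D1:**
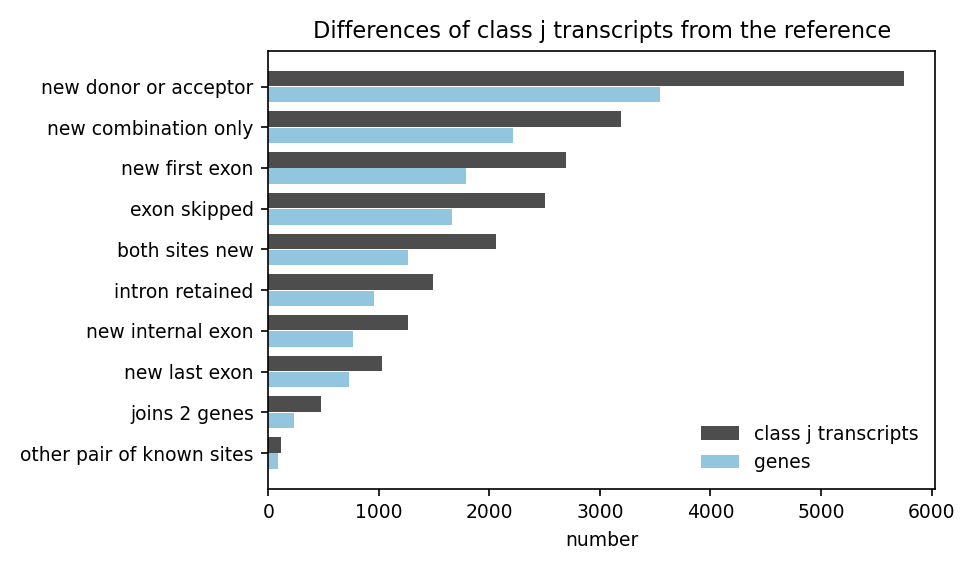
Number of class j transcripts (dark bars) and of genes (light bars) with each kind of difference from the reference; a transcript can hold several. A new donor or acceptor was the most frequent, in 5748 transcripts of 3545 genes.

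Genes of RNA-binding proteins. The comparison addressed whether the gene class the study is about was assembled in new forms more often than like genes. New isoforms were assembled for 291 of 599 RBP genes (48.6%), against a mean of 39.9% in matched random lists (95% range 36.4% to 43.6%), a count above all 10000 of them. Of the 11 RBP lists, 5 lay above their random lists, and none lay below in the main setting. The list of SR proteins and their kinases, which regulate splice site choice, also holds related genes such as LUC7L and SON. This list stood farthest out with 23 of 28 genes (82.1% against 38.9%, percentile 100). Genes for AU-rich element binding and RNA decay had 44 of 73 (60.3% against 45.3%, percentile 99.5), and ribosomal proteins had 33 of 84 (39.3% against 25.7%, percentile 99.7). The excess of the union was not seen among the 96 RBP genes with other assembled evidence (45.8% against 53.6%, percentile 5.78), a restriction chosen after seeing the data. It kept only 44 of the 291 RBP genes with a new isoform. Calls above were lost with a new intron required for the RBM family (percentile 97.3) and ribosomal proteins (13.8), without matching for ribosomal proteins (86.6), and, in settings chosen after seeing the data, without recombined isoforms for the RBM family (96.9) and with a GENCODE 29 intron chain required for SR proteins (97.4), the RBM family (30.0) and other RNA regulators (20.8).

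In the SR protein list, CLK2, a kinase of SR proteins, and SRSF11 had 5 new isoforms each, and LUC7L had 4. All 5 isoforms of CLK2 (chromosome 1, 155232659 to 155243281, minus strand) also held introns of SCAMP3. SRSF11 (chromosome 1, 70671365 to 70717701, plus strand) gained an internal exon of 881 bases at 70696778 to 70697658 in 1 of its 5 isoforms. The exon lay inside an intron of its reference transcripts. Longer exons covered the same stretch in other isoforms, an internal one at 70694105 to 70697658 and a first one at 70696430 to 70698060. Among decay genes, CELF1 had 7, PAN2 6 and CNOT8 5. CELF1 (chromosome 11, 47487489 to 47574792, minus strand), a regulator of splicing and mRNA stability, used a new internal exon of 40 bases at 47528410 to 47528449 in 2 isoforms. All 6 isoforms of PAN2, a subunit of a poly(A) nuclease, also held introns of CNPY2. All 5 of CNOT8, a deadenylase of the CCR4-NOT complex, began in a new first exon.

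**Figure D2:**
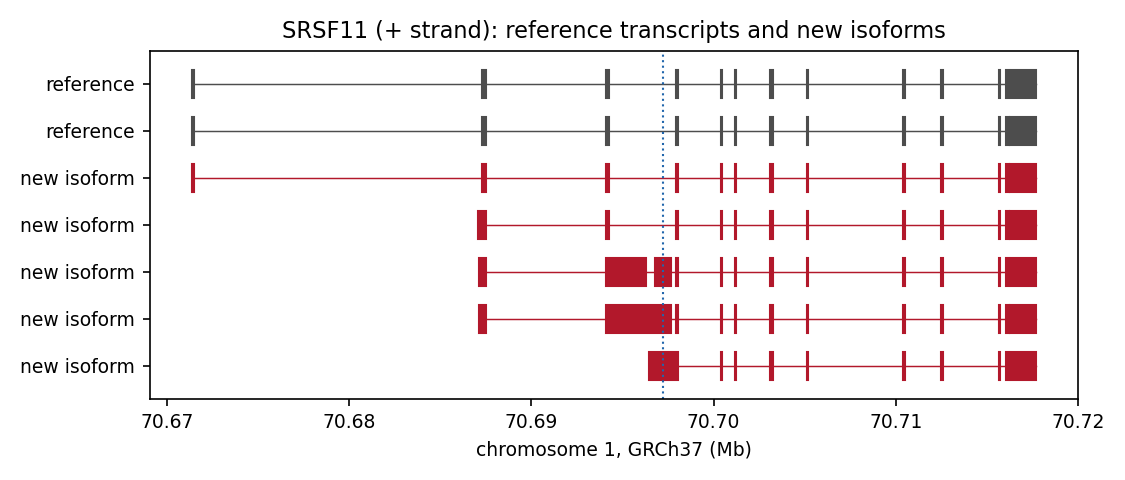
Map of SRSF11 on chromosome 1 (GRCh37, in Mb), with exons as boxes and introns as lines, for the 2 reference transcripts (grey) and 5 new isoforms (red). The dotted line marks the new internal exon of 881 bases, found in 1 of the 5 new isoforms.

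The RBM family had 22 of 42 genes with a new isoform (52.4% against 37.4%, percentile 97.9), among them RBM26 with 5, RBM47 with 4 and RBM33 with 3. RBM26 (chromosome 13, 79894100 to 79979923, minus strand) had a new last exon of 3162 bases downstream of its reference end, at 79885967 to 79889128, in 3 isoforms. The list of other RNA regulators had 53 of 89 (59.6% against 48.0%, percentile 99.1), with 7 isoforms for ATXN2, 6 for STRBP and 5 for LARP1B. In ATXN2, an RNA-binding protein with a polyglutamine tract, 5 isoforms skipped at least 1 exon. Among ribosomal protein genes, RPL10A, RPL13A and RPL3 had 2 each, as did RPS24 and RPS3A. Both isoforms of RPL10A (chromosome 6, 35436178 to 35438558, plus strand) retained the intron at 35436217 to 35436575.

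The other 6 RBP lists lay within their random range. For hnRNPs, 14 of 26 genes had a new isoform (53.8% against 42.2%, percentile 89.0). All 3 isoforms of HNRNPA2B1 (chromosome 7, 26229556 to 26240413, minus strand) and all 3 of HNRNPD held introns with both sites new. In HNRNPA2B1 these lay inside a single reference exon, the last. PTBP2, a repressor of neuronal exons, skipped an exon of 34 bases (chromosome 1, 97271975 to 97272008) in 3 of its 5 isoforms. For the spliceosome the count was 28 of 77 (36.4% against 37.0%, percentile 45.5), with 5 isoforms each for SF1 and USP39. Translation factors had 15 of 55 (27.3% against 38.5%, percentile 3.43) and lay below with a new intron required (1.25) and, chosen after seeing the data, without recombined isoforms (2.08). EIF4G1 had 5 isoforms, all with known introns only, EIF4A2 had 4, and EEF1G had 3, all of which also held introns of TUT1. RNA helicases had 29 of 55 (52.7% against 47.2%, percentile 79.8), among them DDX41 with 4, DDX51 with 3 and DDX17 with 2. Polyadenylation and export genes had 16 of 41 (39.0% against 43.1%, percentile 28.7), led by FIP1L1 with 6 and NXF1 and PABPC4 with 4 each. The m6A and editing list had 14 of 29 (48.3% against 37.6%, percentile 88.9). In this list ADARB1 had 5, and ADAR and ZC3H13 4 each. All 4 isoforms of ZC3H13, a subunit of the m6A writer, ended in a new last exon.

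**Figure D3:**
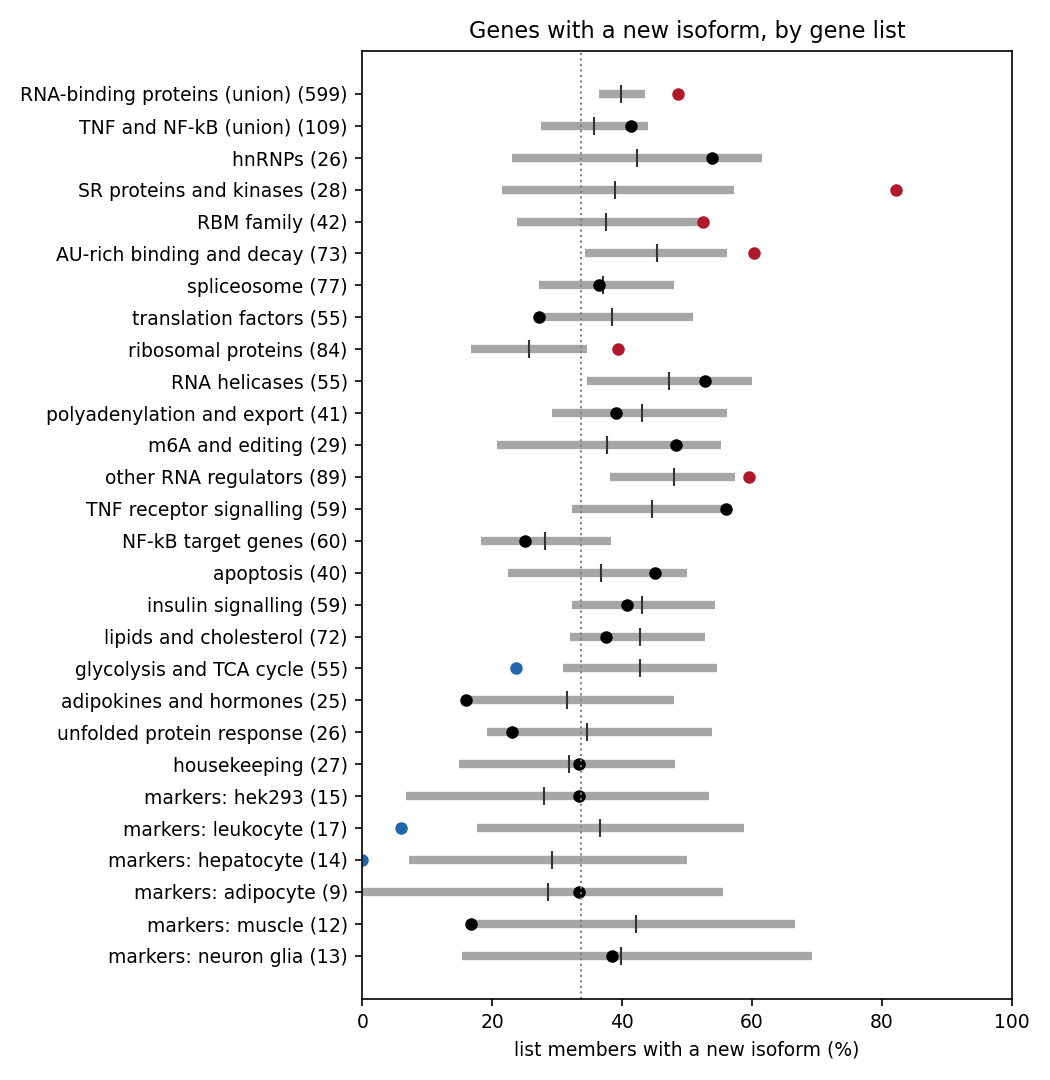
Share of each list's members with a new isoform (points, %; red above, blue below and black within the random lists), with the mean (tick) and 95% range (grey bar) of 10000 matched random lists and, in brackets, the number of members in the background. The dotted line is the share of all background genes (33.6%), and SR proteins and kinases stand farthest above their range at 82.1%.

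Genes of TNF and NF-kB signalling. No new isoform was assembled for TNF (chromosome 6, 31543344 to 31546112, plus strand), TNFRSF1A (chromosome 12, 6437923 to 6451283, minus strand) or TNFRSF1B (chromosome 1, 12227060 to 12269277, plus strand), the cytokine and its receptors. In the union of both lists, 45 of 109 genes had one (41.3% against 35.6%, 95% range 27.5% to 44.0%, percentile 90.7). TNF receptor signalling genes had 33 of 59 (55.9% against 44.6%, percentile 96.8), and NF-kB target genes had 15 of 60 (25% against 28.1%, percentile 29.1). The receptor signalling list was above without matching (percentile 99.99) and in 3 settings chosen after seeing the data.

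MAPK8, the stress kinase JNK1, had the most isoforms of the receptor signalling genes, 6. All 6 began in new first exons upstream of the reference start (chromosome 10, 49609687 to 49643183, plus strand), at 49514705 or 49514722 to 49514864. CASP8 and CYLD, a caspase of death receptor signalling and a deubiquitinase, had 4 each. In CASP8, 1 isoform ended in a new last exon at 202104993 to 202106933 on chromosome 2. Among NF-kB targets, BCL2L1 had 5 isoforms, 4 of them with a new first exon near 30310220 to 30311760 on chromosome 20, and LIF and NFKB2 had 2 each. Of genes chosen after their values were seen, the IkB kinase subunit IKBKB had 4 isoforms, and NFKBIA, ICAM1, IL6 and CCL2 had none.

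Metabolic genes and markers. The glycolysis and TCA cycle list lay below its random lists, with a new isoform in 13 of 55 genes (23.6% against 42.7%, percentile 0.095). ENO3, a muscle enolase, had 4, PFKM 3 and LDHA 2, and all 3 isoforms of PFKM, the muscle phosphofructokinase, skipped an exon of 93 bases (chromosome 12, 48529074 to 48529166). Insulin signalling had 24 of 59 (40.7% against 43.1%, percentile 34.5), among them GRB10 and RICTOR with 3 isoforms each. Lipid and cholesterol genes had 27 of 72 (37.5% against 42.7%, percentile 17.1). All 4 isoforms of ACADVL, a mitochondrial fatty acid dehydrogenase, retained an intron, and ACACB and ELOVL6 had 3 isoforms each. Adipokines and metabolic hormones had 4 of 25 (16.0% against 31.5%, percentile 3.33), led by TCF7L2 with 6 and LEPR and NAMPT with 2 each. The unfolded protein response list had 6 of 26 (23.1% against 34.6%, percentile 9.99), among them ATF6 and SYVN1 with 2 each and CALR with 1. Apoptosis genes had 18 of 40 (45.0% against 36.7%, percentile 86.9), among them BIRC6 with 6 isoforms and BCL2L1 with 5. Housekeeping genes had 9 of 27 (33.3% against 31.9%, percentile 57.5), led by POLR2A and VCP with 3 each and GUSB with 2. The glycolysis list was within the random range without matching (percentile 5.93) and, chosen after seeing the data, with a GENCODE 29 intron chain required (30.5). Its 7 genes with other assembled evidence, also chosen after seeing the data, were too few to decide (2 of 7, percentile 8.20, random range 14.3% to 85.7%).

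HEK293 markers had 5 of 15 genes with a new isoform (33.3% against 28.0%, percentile 68.8), with 4 isoforms for MIAT and 1 each for KRT18 and NEFH. Leukocyte markers had 1 of 17 (5.88% against 36.5%, percentile 0.135). That gene was LCP1, an actin-bundling protein, with 2 isoforms. Hepatocyte markers had 0 of 14 (29.2% in random lists, percentile 0.37). Muscle markers had 2 of 12 (16.7% against 42.1%, percentile 2.70), TTN with 4 isoforms and TNNT1 with 2. Adipocyte markers had 3 of 9 (33.3% against 28.6%, percentile 63.6), LIPE with 3 and CFD and PPARG with 1 each. Neuron and glia markers had 5 of 13 (38.5% against 39.8%, percentile 46.8), led by GAD1 with 5, MAP2 with 4 and MBP with 3. In all, 5 of the 26 lists lay above and 3 below, where chance alone gives 0.65 on each side. With a GENCODE 29 intron chain required, leukocyte markers (percentile 14.1) and hepatocyte markers (19.5) were within the random range. Only 6.99% of background genes qualified in that setting, where lists this small can hardly be called below. Hepatocyte markers, already at 0 of 14, could not go lower, so the setting cannot decide whether their call holds.

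Intergenic and antisense transcripts. The catalogue held 5580 class u transcripts in 5344 loci. Of these transcripts, 14 overlapped the span of a reference gene, and 5027 (90.1%) had a single exon, with a median of 1146 bases. The 553 transcripts of 2 or more exons included the 3 loci with the most exons. One on chromosome 7 (6677017 to 6696275, plus strand) had 9 exons and lay 13096 bases downstream of ZNF853, a zinc finger gene. One on chromosome 2 (239067651 to 239077467, plus strand) had 8 exons and lay 1576 bases from ILKAP on the opposite strand. One on chromosome 10 (67330310 to 67419587, plus strand) had 7 exons, and the nearest gene was CTNNA3 at 260138 bases. Class x transcripts, 565 in 413 genes, lay opposite to exons, and 447 of them had a single exon.

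Strand was related to the nearest gene downstream, and upstream mainly at under 2 kb. Of single-exon transcripts downstream of a gene, 2313 lay on the strand of the gene and 668 on the other (77.6% on the same strand, 95% Wilson interval 76.1% to 79.1%). The share was 66.4% at under 2 kb, 85.2% between 2 and 10 kb and 70.6% at 10 kb or more. Upstream of a gene at under 2 kb the order was turned, with 189 on the same strand and 455 on the opposite strand (29.3% on the same strand, 26% to 33.0%). Farther upstream the same-strand share was 44.7% at 2 to 10 kb and 49.7% at 10 kb or more. Transcripts of 2 or more exons at under 2 kb upstream were opposite to the gene in 151 cases and on its strand in 19 (11.2% on the same strand, 7.27% to 16.8%). Their same-strand share was 51.9% at 2 to 10 kb upstream and 54.3% at 10 kb or more. Downstream on the same strand, the number of transcripts stepped from 41 at 1500 to 2000 bases to 198 at 2000 to 2500 bases, while it was 33 and 32 on the opposite strand.

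**Figure D4:**
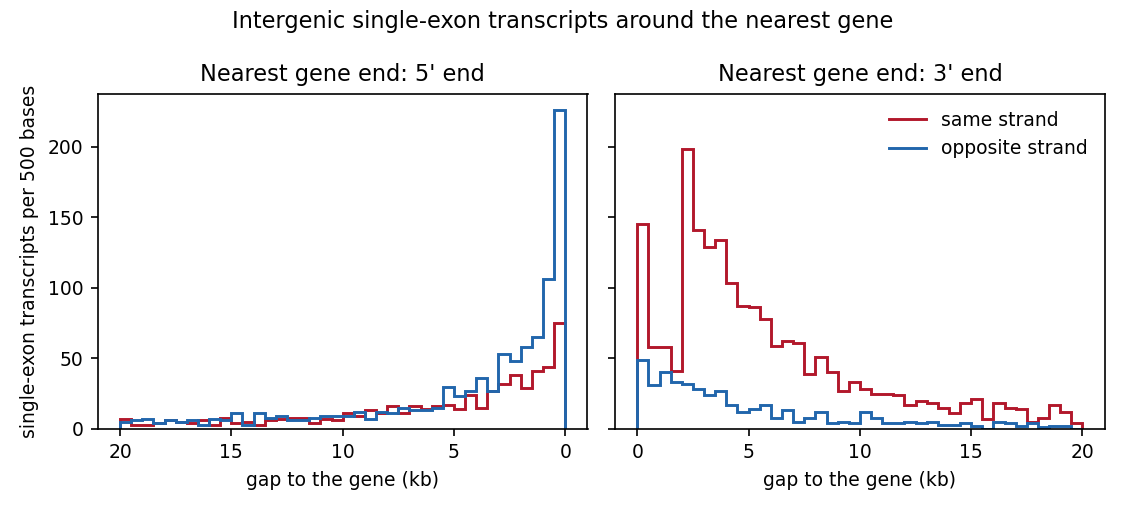
Number of intergenic single-exon transcripts per 500 bases (vertical axis) by the gap to the nearest gene in kb, for transcripts nearest to a 5′ end (left) and a 3′ end (right), on the strand of the gene (red) or opposite to it (blue). Opposite transcripts gather at 5′ ends and same-strand transcripts at 3′ ends, where their number steps from 41 to 198 at 2 kb.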

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

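The settings that require the intron chain of a GENCODE 29 transcript and that match on genomic span were chosen after seeing the data. So was the setting without recombined isoforms, which hold reference introns only and no other difference. The count of 6793 genes with a new isoform was 5059 with a new intron required, 6556 with at least 3 exons, 6728 by locus, 7051 with classes j, o and x together and 5494 without recombined isoforms, but 1412 with the GENCODE 29 chain, where fewer transcripts could qualify. Apart from the restriction to genes with other assembled evidence (5.78), the RBP union stayed above in the settings run, at percentiles of 97.6 to 100, lowest with the GENCODE 29 chain, and the TNF and NF-kB union stayed within, at 77.7 to 96.5. The number of lists above was 5, and 3 with a new intron required, 3 with the GENCODE 29 chain, 5 without recombined isoforms, 6 with span matching and 7 without matching. With the GENCODE 29 chain, other RNA regulators fell to percentile 20.8 and the RBM family to 30.0, and the cause was not tested. With a new intron required, ribosomal proteins fell to 13.8, since isoforms that differ only by a retained intron bring no new intron. Over single lists and these settings, 111 percentiles kept their call, 8 gained one and 11 lost one, 3 of these moving to the other side of the random mean. The receptor signalling list gained its call without matching (99.99), with span matching (98.8), with the GENCODE 29 chain (97.6) and without recombined isoforms (98.7). Without matching, hnRNPs (98.1) and RNA helicases (99.8) were above. Of 5580 class u transcripts, 553 had 2 or more exons, fewer by construction, and 5454 had at least 200 bases. The share of splice site sequences in new introns, the alternative for introns of at least 50 bases and the settings for a value per library were not run. Unknown read depth limits what the absence of an isoform shows. No paired analysis was possible because each group held 1 library.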

Other observations

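The comparisons of single kinds of difference, with GENCODE 29 and of introns that hold small nucleolar RNAs were chosen after seeing the data. So were the tests below, but the results of 2 of them, on RBP genes with other assembled evidence and on introns inside exons, had not been seen when they were set. The RBP excess differed by kind of difference. Fewer RBP genes than expected skipped an exon (33 against 60.5 in matched random lists, percentile 0), and more had an intron with both sites new (80 against 40.9, percentile 100), a new donor or acceptor (141 against 122, percentile 97.7) or a retained intron (57 against 34.7, percentile 100). Without ribosomal proteins and translation factors, introns with both sites new (67 against 32.7, percentile 100) and new donors or acceptors (134 against 101, percentile 99.99) stayed above, and retained introns did not (35 against 28.8, percentile 89.1). Retained introns stood out in ribosomal protein genes, with 20 of 84 genes against 2.85, among them RPL10A, RPL3, RPL7A and RPS3A, while new donors or acceptors were fewer (2 against 10.8, percentile 0.035). Small nucleolar RNAs, which are processed from introns of ribosomal protein genes, lay in 7 of 30 of these retained introns, 4 of them overlapping introns of RPL17, and in 56 of 398 other introns of the list. Over all genes they lay in 17 of 1396 retained introns (1.22%), these 7 included, and in 0.135% of other introns, with overlapping introns counted separately. RNA helicases skipped an exon in 1 gene against 8.06. Isoforms with introns of a second gene were also found in more genes of the RBP union (15 against 8.44, percentile 98.6). They stayed above without ribosomal proteins and translation factors (13 against 7.18, percentile 97.8), where new internal exons were above too (35 against 21.8, percentile 99.7). Over all 290 pairs of a list and a kind of difference, 24 lay above and 16 below.

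In the SR protein list, 8 of 28 genes had a new internal exon against 1.07 expected (percentile 100). The 9 exons lay in SRSF1, SRSF11, SRSF12, TRA2A, TRA2B, SRRM1, SRPK2 and LUC7L. In TRA2B, a splicing activator, the exon had 276 bases (chromosome 3, 185649365 to 185649640, minus strand), and in TRA2A it had 312 bases (chromosome 7, 23561740 to 23562051, minus strand). The exon with both flanking introns had the lengths of a GENCODE 29 exon of the same gene in 5 of the 9 cases, TRA2A, TRA2B, SRRM1, SRPK2 and LUC7L, and in 573 of 972 new internal exons of all genes (59.0%). Single exons skipped by a new intron had a length that is a multiple of 3 in 50.7% of 1695 cases (48.3% to 53.1%), against 40.3% of other internal exons of the same genes (39.6% to 41.0%). Among the genes named by rule, isoforms of NXF1 joined TMEM223 and STX5, and isoforms of DDX41 joined DOK3.

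The first pattern is the excess of new isoforms in RBP genes. Isoforms that the merge makes by recombining reference introns cannot be the whole source, since the percentile of the union without them was 100. That more RBP genes are transcribed in HEK293 remains a candidate explanation. Among genes with an assembled class = transcript or a same-strand transcript within 10 kb downstream, the union was at percentile 5.78 (44 of 96 genes, 45.8% against 53.6%). RBP genes had such evidence more often (16.0% against 10.6% of the background), but these shares were not matched on exon or reference transcript number. Such evidence covered 2148 of 20209 background genes and only 44 of the 291 RBP genes with a new isoform. It therefore does not mark transcribed genes as a whole, and the result cannot decide for the genes outside it. The smaller union without ribosomal proteins and translation factors was likewise not above (percentile 20.3, 50% against 54.2%), but transcription of single genes was not measured, and SR proteins, with 5 of 5 such genes (percentile 98.4, random range 0% to 100%), were too few to decide. An effect of TNF alpha was not tested, since no transcript is tied to a library.

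For the second pattern, the new introns and combinations, errors of alignment or assembly cannot be the whole source of the introns, since 54.6% of new introns in named genes had an equally long intron in the same GENCODE 29 gene, against 0.320% in another gene and 97.9% for reference introns. The share was 42.5% for introns with both sites new, and whole intron chains matched in 12.8% of class j and 86.6% of reference transcripts. Introns inside a single reference exon, as in MKI67, PRPF4B, AHNAK and HNRNPA2B1, were less often found there (36.6%, 32.5% to 41.0%) than the other new introns (55.8%, 54.7% to 56.8%), a comparison that covers 486 of the 539. With 1 or 2 reference transcripts, new combinations were more frequent with a new intron than without (11.8% against 4.14%, difference 7.69 percentage points). Genes with 1 had no second transcript to join, so they cannot decide on joining by the merge without reads. In genes with 2, the shares were 15.7% (13.7% to 17.9%) against 7.59% (6.68% to 8.61%). These shares were not matched on exon number. Genes with 1 showed an excess too (10.3% against 3.07%), where no joining is possible. The contrast therefore cannot decide on joining in genes with 2. Part of these isoforms may follow 1 reference chain with a changed end. Joining may act in genes with 6 or more, which showed no such excess (43.4% against 48.9%, a difference of -5.44 percentage points). Joining also stays open for 3 (26.9% against 22.1%) and 4 to 5 (36.2% against 32.7%). The intervals overlap in all 3 of these classes, and no biological explanation was tested.

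In the third pattern, the strand of single-exon transcripts downstream of genes, genomic DNA or reads without strand would fall equally on both strands, and 77.6% lay on the strand of the gene. Known longer 3′ ends account for a small part of the transcripts that are in the catalogue. Of 1398 comparable same-strand transcripts within 10 kb, 12.7% (11.1% to 14.6%) began inside the GENCODE 29 last exon that follows the same intron. On the opposite strand the share was 4.81%. Transcription past the annotated end may account for part of the rest, but it was not measured. Of the nearest genes within 10 kb, 52.9% (49.8% to 56.0%) had a new isoform, against 33.2% for opposite-strand transcripts (27.8% to 39.1%). The share was also over that of the background (33.6%) for genes with transcripts upstream, 46.1% on the same strand and 45.4% on the opposite strand, so it is not specific to 3′ ends. These shares were not matched on exon or reference transcript number. A removal by the merge of same-strand transcripts within 2000 bases was not tested. It would lower the counts there, and with them the number that could begin inside a longer last exon. A biological explanation from the design was not tested either.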
